A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

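The study measured transcripts of Saccharomyces cerevisiae strain S288C on 2-colour arrays after 4 kinds of radiation, with 3 arrays for each. The 12 arrays gave 21 columns of values, since the 9 arrays of carbon ions, thermal neutrons and fast neutrons were scanned at high and at low laser power. The values are deposited log2 ratios of the 2 channels of each array, and the labels state that spots with flag value 0 entered the LOWESS normalisation. The log base is not stated in the labels. It was settled from the values, because 4 columns have their minimum at log2 of a ratio of 0.01. Each column had a mean within 0.01 of 0. The ratio was read as irradiated (Cy5) over unirradiated control (Cy3) from the channel order in the labels, and HUG1, RNR2 and RNR4, which are induced by DNA damage, were positive on all 12 arrays under this reading. No dye was swapped, so a gene's dye effect is part of every ratio against 0 and cancels in a difference between radiations of the same table. The labels mention values merged in GeneSpring, which were not used here.

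Gamma rays, carbon ions and thermal neutrons share 1 table of values (9 arrays), and fast neutrons have a table of their own on another array type (3 arrays). Each table has 6912 probes. In the first, 5446 probes carried 1 gene symbol and 1466 carried none, and in the second these numbers were 5513 and 1399. The 2 scans of an array were averaged for each probe, then the probes of a gene, to give 1 value per gene and array. Probes with no symbol were tested apart. Between 4496 and 6133 probes per column held a value. The 2 scans of an array correlated across probes with r between 0.69 and 0.96. The lowest values were 0.693 for fast neutrons replicate 2 and 0.698 for carbon ions replicate 3. The high-power scan of fast neutrons replicate 2 had a median log2 ratio of 0.134, while the medians of the other 20 columns lay between -0.0397 and 0.0049. Replicate numbers do not pair the samples: residuals of arrays with the same number correlated across genes with r between -0.26 and 0.13 in 9 pairs. The number of arrays limits the precision.

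Each radiation was tested against 0 with limma (version 3.58.1, R 4.3.3; lmFit and eBayes, two-sided) on genes with a value on all 3 of its arrays, with the Benjamini-Hochberg adjusted p under 0.05 as threshold. The 9 arrays of the first table shared 1 estimate of the spread, and fast neutrons were fitted alone. Differences between gamma rays, carbon ions and thermal neutrons were limma contrasts. Fast neutrons were not tested against the others, since the tables were made on different array types, and are set beside them only. Gene lists with at least 5 measured members, out of lists fixed before the data were examined, were tested with camera (cameraPR in limma, on the moderated statistics) with a preset inter-gene correlation of 0.01. Camera with the correlation estimated from residuals was run beside it, with an estimate below 0 set to 0. In the table of 9 arrays the estimate was 0 for the DNA damage inducible, ubiquitin and autophagy, and sulfur assimilation lists. For these lists the second run is less strict than the main test. For fast neutrons the estimate comes from 3 arrays only. Fry was also run: its first p tests whether a list's genes move, on balance, one way, its mixed p tests whether they change in either direction, and neither compares the list with other genes. Set tests of the differences were added after the data had been seen. Counts of list members are given over all genes tested and adjusted over the list alone.

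Genes were named by a rule fixed before the data were examined. For each radiation it takes the 12 highest and 12 lowest mean log2 ratios among genes that pass and have the same sign on all 3 arrays. For each difference it takes the 5 largest in each direction, and for each list up to 4 members with the smallest p. Any measured member of the DNA damage inducible list may be named. Among the genes the rule allows, the text mostly names those that passed under every alternative tried, a choice made after the values were seen.

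The fit was tested on simulated data with known changes. In the design of 9 arrays, 46.3% of genes changed by log2 0.5, 97% of those changed by 1 and 97% of those changed by 2 were recovered against 0, and 7.51% of calls were false. For a difference between 2 radiations the values were 7.46%, 67.2% and 97%, with 6.56% false. With 3 arrays alone they were 1.49%, 49.3% and 92.4%, with 3.06% false. In each design 67, 67 and 66 genes were changed by log2 0.5, 1 and 2. This is a smaller share of the genes than passed in the measured values, and no dye effect was simulated. The recovered and false shares therefore do not carry over to the measured fits. A shifted list of 40 members was found in 20 of 20 runs, and 0 of 720 other lists were called. The simulated genes varied independently and the lists were drawn at random. These runs therefore do not show how often camera with the preset correlation calls a list of correlated genes falsely. In the measured values the estimated correlation was 0.473 for hexose transport and 0.242 for the proteasome.

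The alternatives were each scan alone, median centring, scaling of the arrays to the same spread (normalizeMedianAbsValues, which is limma's scale method for log ratios), genes with a value on at least 2 arrays, each probe on its own, the arrays of 1 radiation alone, robust eBayes, array weights, the replicate number as a block, stricter thresholds, ranks or an estimated correlation in the set test, and leaving out each replicate. Leaving out the high-power scan that correlated least with its partner was chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Gene names are those of the reference tables, and the genome build is not given in the sources used here.

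Some values in the labels do not match each other. Gamma rays are given as 17 Gy over 20.5 h beside a rate of 1.4 Gy/min. Fast neutrons are given as 20.3 Gy over 19 h beside 21.4 Gy in 336 min at 0.064 Gy/min. Thermal neutrons are given as 20.8 Gy over 20 h with a global rate of 17 mGy/min, which nearly match. Of that rate 1.0 to 2.0 mGy/min came from thermal neutrons. Carbon ions are given as 25 Gy in 10 min at 3 Gy/min. Doses are quoted as labelled.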

Results

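Transcript levels were compared between irradiated yeast and unirradiated control cultures on 12 arrays. There were 3 arrays each for gamma rays (17 Gy), carbon ions (25 Gy, 290 MeV per nucleon), thermal neutrons (20.8 Gy) and fast neutrons (20.3 Gy). By the labels only 1.0 to 2.0 of the 17 mGy/min given to the thermal neutron group came from thermal neutrons. Its values therefore cannot be read as the effect of thermal neutrons alone. Cells were irradiated cold in saline and then recovered for 40 min in 50 ml of rich medium at 25 C before RNA was taken. Values are mean log2 ratios of irradiated over control ± SD over 3 arrays (n = 3), unless a fold is given. Each gene printed with an SD had the same sign on all 3 arrays of that radiation. The comparisons ask which transcripts change after each radiation and how the radiations differ. Replicate arrays correlated across genes with r from 0.73 to 0.84 for gamma rays, 0.44 to 0.71 for carbon ions, 0.74 to 0.86 for thermal neutrons and 0.43 to 0.69 for fast neutrons. Genes are not independent replicates.

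After gamma rays, PHO89 (YBR296C), a sodium and phosphate cotransporter, rose 12.4-fold (3.63 ± 0.22, adjusted p = 1.2e-06). NCE103 (YNL036W), carbonic anhydrase, reached 3.39 ± 0.24. JEN1 (YKL217W), the lactate permease, reached 3.18 ± 0.47, SUC2 (YIL162W), invertase, 2.95 ± 0.43, and MAL12 (YGR292W), a maltase, 2.79 ± 0.07. Among hexose transport genes 15 of 22 rose and 0 fell (16 and 1 adjusted over the list alone), among them HXT5 (2.42 ± 0.37), HXT13 (2.42 ± 0.40) and HXT16 (1.96 ± 0.41). The hexose list had a median of 1.03 (camera adjusted p = 1.8e-08; adjusted p = 0.17 with an estimated correlation). In the stationary phase list 18 of 23 members rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.83 (adjusted p = 4.1e-07; 0.021 with an estimated correlation), and SPG1, needed for survival in stationary phase, was at 2.98 ± 0.18. Nuclear genes of respiration rose in 24 of 50 and fell in 1 (27 and 1 adjusted over the list alone), with NDI1 and NDE2, NADH dehydrogenases, at 1.27 ± 0.13 and 1.37 ± 0.25. Their median was 0.34 (adjusted p = 1.6e-06; 8.4e-05 with an estimated correlation). Stress-induced genes rose in 33 of 58 and fell in 3 (34 and 3 adjusted over the list alone), including GDB1 and GPH1, which break down glycogen (2.09 ± 0.21 and 1.95 ± 0.08). Their median was 0.57 (adjusted p = 1.8e-08; adjusted p = 0.1 with an estimated correlation).

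Of the DNA damage inducible genes, 15 of 33 rose after gamma rays and 2 fell (19 and 3 adjusted over the list alone). HUG1 (YML058W-A), an inhibitor of ribonucleotide reductase, rose 3.92-fold (1.97 ± 0.20). RNR4 (YGR180C) and RNR2 (YJL026W), the small subunits of that enzyme, rose to 1.38 ± 0.18 and 1.33 ± 0.15, and RNR3, its damage-induced large subunit, to 1.56 ± 0.55. RNR1 (YER070W), the main large subunit, was at -1.83 ± 0.07. The list median was 0.48 (adjusted p = 3.7e-04; 1.1e-04 with an estimated correlation).

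UTP15 (YMR093W) and SOF1 (YLL011W), of the small subunit processome, fell after gamma rays and were at -1.92 ± 0.14 and -1.86 ± 0.28. Of the ribosome biogenesis list 33 of 74 members fell and 3 rose (34 and 4 adjusted over the list alone), with a median of -0.40 (adjusted p = 0.0022; adjusted p = 0.51 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 39 of 69 and rose in 1 (45 and 1 adjusted over the list alone), among them MRP2 (-1.15 ± 0.07), with a median of -0.45 (adjusted p = 1.9e-06; adjusted p = 0.14 with an estimated correlation). Cytosolic ribosomal protein genes fell in 40 of 124 and rose in 1 (37 and 1 adjusted over the list alone), with RPL22A at -0.97 ± 0.07 and a median of -0.18 (adjusted p = 0.0019; adjusted p = 0.34 with an estimated correlation). Of the chaperone genes 22 of 39 fell and 1 rose (22 and 1 adjusted over the list alone). HSC82 and HSP82, the Hsp90 proteins, were at -1.48 ± 0.09 and -1.29 ± 0.13, and their cochaperones AHA1 (YDR214W) and HCH1 (YNL281W) at -1.72 ± 0.22 and -1.91 ± 0.46. The chaperone median was -0.47 (adjusted p = 2.6e-05; adjusted p = 0.1 with an estimated correlation). Proteasome genes fell in 18 of 37 and rose in 0 (22 and 1 adjusted over the list alone), with PUP1 at -0.63 ± 0.16 and a median of -0.37 (adjusted p = 2.3e-04; adjusted p = 0.34 with an estimated correlation). TYE7 (YOR344C), an activator of glycolytic genes, was the lowest named gene at -2.23 ± 0.24.

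Sporulation genes rose in 10 of 21 and fell in 0 (10 and 0 adjusted over the list alone), with IME2, a meiotic kinase, at 1.11 ± 0.15 and a median of 0.44 (adjusted p = 0.0059; adjusted p = 0.1 with an estimated correlation). RNA polymerase I and III genes fell in 8 of 21 and rose in 0 (8 and 0 adjusted over the list alone), with a median of -0.33 (adjusted p = 0.022; adjusted p = 0.34 with an estimated correlation).

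In limma, 1958 of 4891 genes passed after gamma rays, 862 higher and 1096 lower, and 343 of them changed at least 2-fold. With each array centred on its median the majority turned, with 987 higher and 943 lower. Of 36 lists, 7 shifted up and 9 down, and 3 of these 16 (respiration, DNA damage inducible and stationary phase) were also called with an estimated correlation. The calls for amino acid biosynthesis (median -0.28) and for G2/M genes (-0.37) ended without replicate 1 (adjusted p = 0.062 for each), and the latter also without replicate 2 (0.075). Cell wall integrity (0.28) was no longer called without replicate 2 (0.11) or 3 (0.1), and purine biosynthesis (-0.33) without replicate 2 or 3 (0.054 each). The corresponding adjusted p with an estimated correlation was 0.48, 0.34, 0.48 and 0.14.

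After carbon ions HUG1 rose 8.63-fold (3.11 ± 0.25, adjusted p = 1.8e-07), RNR4 6.48-fold (2.70 ± 0.18) and RNR2 5.41-fold (2.44 ± 0.21). Between RNR4 and RNR2 lay TMA10 (YLR327C), of unknown function (2.62 ± 1.06), and YNL194C, a membrane protein (2.50 ± 0.79). DDR2 (YOL052C-A), a stress gene first found by its response to DNA damage, rose to 1.98 ± 0.08. Of the DNA damage inducible genes 14 of 32 rose and 0 fell (14 and 2 adjusted over the list alone), with a median of 0.32 (adjusted p = 4.2e-05; 1.3e-05 with an estimated correlation). Stress-induced genes rose in 43 of 54 and fell in 0 (48 and 0 adjusted over the list alone), among them HSP12 (YFL014W), a membrane-protecting protein (1.98 ± 0.33), and TFS1, an inhibitor of carboxypeptidase Y (1.56 ± 0.15). Their median was 0.91 (adjusted p = 2.9e-27; 5.0e-05 with an estimated correlation). Genes of oxidative stress defence rose in 19 of 40 and fell in 3 (20 and 7 adjusted over the list alone), with SOD1, superoxide dismutase, at 1.16 ± 0.11 and AHP1, a peroxiredoxin, at 1.19 ± 0.23. Their median was 0.28 (adjusted p = 3.0e-04; adjusted p = 0.18 with an estimated correlation). Cytosolic ribosomal protein genes rose in 33 of 124 and fell in 0 (42 and 2 adjusted over the list alone), with RPL25 at 0.91 ± 0.20, RPS26A at 1.03 ± 0.16 and a median of 0.28 (adjusted p = 4.3e-09; 0.034 with an estimated correlation). Nuclear genes of respiration rose in 15 of 50 and fell in 0 (19 and 0 adjusted over the list alone), with CYC7, a cytochrome c isoform, at 1.28 ± 0.17 and a median of 0.26 (adjusted p = 1.5e-05; 2.2e-04 with an estimated correlation).

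Most genes of the M/G1 list, which holds genes for the separation of mother and daughter cells, fell after carbon ions. SCW11 (YGL028C), a cell wall glucanase, was at -1.98 ± 0.29, CTS1 (YLR286C), the chitinase of cell separation, at -1.41 ± 0.07, and the daughter-specific genes DSE1 (YER124C) and DSE2 (YHR143W) at -1.78 ± 0.22 and -1.72 ± 0.18. In that list 15 of 22 members fell and 1 rose (16 and 2 adjusted over the list alone), with a median of -0.66 (adjusted p = 1.8e-07; 6.6e-04 with an estimated correlation). HO (YDL227C), the mating type endonuclease, was at -2.06 ± 0.40 and CLN2 (YPL256C), a G1 cyclin, at -1.90 ± 0.17. G1/S genes fell in 17 of 36 and rose in 1 (17 and 1 adjusted over the list alone), with a median of -0.45 (adjusted p = 4.2e-05; adjusted p = 0.18 with an estimated correlation). Of the G2/M genes 10 of 18 fell and 0 rose (10 and 0 adjusted over the list alone), with CLB1, a mitotic cyclin, at -1.22 ± 0.64 and a median of -0.40 (adjusted p = 3.9e-04; adjusted p = 0.078 with an estimated correlation). Ribosome biogenesis genes fell in 25 of 88 and rose in 0 (26 and 0 adjusted over the list alone), with a median of -0.36 (adjusted p = 1.8e-07; adjusted p = 0.24 with an estimated correlation). Amino acid biosynthesis genes fell in 20 of 59 and rose in 1 (25 and 3 adjusted over the list alone), among them LEU9 (-0.82 ± 0.09) and HIS5 (-0.70 ± 0.16), with a median of -0.32 (adjusted p = 2.7e-05; adjusted p = 0.18 with an estimated correlation). DNA replication genes fell in 6 of 38 and rose in 0 (6 and 0 adjusted over the list alone), with PSF3, of the GINS complex, at -0.55 ± 0.11 and a median of -0.25 (adjusted p = 0.0014; adjusted p = 0.18 with an estimated correlation). The lists for glycolysis, hexose transport and proteasome shifted up, with medians of 0.23, 0.41 and 0.24 (adjusted p = 0.0012, 0.0014 and 0.0016; with an estimated correlation adjusted p = 0.19, 0.4 and 0.35). The mitochondrially encoded transcripts, which priming on a poly(A) tail should deplete, had a median of -0.47 on the same arrays and were not called (adjusted p = 0.13).

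In limma, 1105 of 5095 genes passed after carbon ions, 495 higher and 610 lower, and 124 changed at least 2-fold. With median centring 577 were higher and 477 lower, so that the majority turned. The count was 399 without replicate 1 and 371 without replicate 2, 532 with the carbon ion arrays fitted alone, 1675 with arrays scaled to the same spread and 2165 with array weights. Of 37 lists, 10 shifted up and 7 down, and 5 of the 17 (stress-induced, DNA damage inducible, M/G1, cytosolic ribosomal proteins and respiration) were also called with an estimated correlation. The call for RNA polymerase I and III (median -0.27) ended without replicate 2 (adjusted p = 0.18), as did that for stationary phase (0.14; adjusted p = 0.41). Ubiquitin and autophagy (0.12) was no longer called without replicate 1, 2 or 3 (0.092, 0.088 and 0.064). The adjusted p with an estimated correlation was 0.35, 0.25 and 0.066.

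After thermal neutrons, most chaperone genes rose. SSA4 (YER103W), a heat-induced Hsp70, rose 28.6-fold (4.84 ± 0.16, adjusted p = 3.5e-10). HSP42 (YDR171W), a small heat shock protein, rose 17.3-fold (4.11 ± 0.11), and HSP104 (YLL026W), the disaggregase, 15.3-fold (3.94 ± 0.42). HSP26 (YBR072W), another small heat shock protein, was at 3.01 ± 0.75 and HSP78 (YDR258C), a mitochondrial disaggregase, at 2.78 ± 0.33. Of the chaperone genes 30 of 39 rose and 4 fell (32 and 4 adjusted over the list alone), with a median of 0.79 (adjusted p = 4.8e-13; 0.001 with an estimated correlation). Proteasome genes rose in 36 of 37 and fell in 0 (36 and 0 adjusted over the list alone), with RPT1 at 1.23 ± 0.16, PUP1 at 1.10 ± 0.09 and a median of 1.02 (adjusted p = 4.3e-18; 0.0052 with an estimated correlation). Genes of ubiquitin and autophagy rose in 20 of 28 and fell in 2 (21 and 2 adjusted over the list alone), including ATG8 (YBL078C), which builds the autophagosome (2.13 ± 0.41), and UBC5 (1.28 ± 0.21). Their median was 0.54 (adjusted p = 8.3e-07; 6.4e-08 with an estimated correlation). Stress-induced genes rose in 47 of 59 and fell in 2 (49 and 2 adjusted over the list alone), with a median of 0.92 (adjusted p = 4.3e-18; 0.0021 with an estimated correlation). MET17 (YLR303W), homocysteine synthase, reached 2.71 ± 0.41 and ARO9 (YHR137W), an aromatic aminotransferase, 2.55 ± 0.42.

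Of the DNA damage inducible genes 18 of 35 rose after thermal neutrons and 1 fell (18 and 2 adjusted over the list alone). RNR4 rose to 1.77 ± 0.07, HUG1 to 1.60 ± 0.08, DDI1 to 1.74 ± 0.30, MAG1, a DNA glycosylase, to 1.60 ± 0.32, and RAD54, a recombination ATPase, to 1.04 ± 0.05. The median was 0.54 (adjusted p = 2.7e-05; 3.5e-06 with an estimated correlation). RFA1 and RFA3, subunits of the single-strand binding protein RPA, rose to 1.51 ± 0.22 and 1.12 ± 0.00. Oxidative stress defence genes rose in 25 of 41 and fell in 5 (25 and 5 adjusted over the list alone), with PRX1 at 1.85 ± 0.15 and a median of 0.61 (adjusted p = 3.7e-06; adjusted p = 0.095 with an estimated correlation). Genes of the phosphate regulon rose in 13 of 18 and fell in 0 (14 and 0 adjusted over the list alone), with SPL2 at 1.83 ± 0.06, PHO89 at 1.82 ± 0.53 and a median of 0.81 (adjusted p = 2.6e-06; 0.02 with an estimated correlation).

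Most hexose transport genes fell after thermal neutrons. The hexose transporters HXT1 (YHR094C), HXT2 (YMR011W), HXT3 (YDR345C) and HXT4 (YHR092C) were at -2.10 ± 0.38, -2.14 ± 0.69, -1.90 ± 0.39 and -2.13 ± 0.53. In that list 15 of 21 members fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.86 (adjusted p = 2.3e-05; adjusted p = 0.24 with an estimated correlation). OLE1 (YGL055W), the fatty acid desaturase, was at -2.49 ± 0.04, while OPI3 (YJR073C), a methyltransferase of phosphatidylcholine synthesis, rose to 2.19 ± 0.14. Ergosterol genes fell in 15 of 26 and rose in 1 (16 and 1 adjusted over the list alone), with ERG3 at -1.34 ± 0.43 and a median of -0.39 (adjusted p = 3.8e-04; adjusted p = 0.12 with an estimated correlation). Ribosome biogenesis genes fell in 28 of 88 and rose in 0 (25 and 0 adjusted over the list alone), with DBP2 at -1.47 ± 0.13 and a median of -0.39 (adjusted p = 3.7e-06; adjusted p = 0.28 with an estimated correlation). The G1 cyclins CLN1 and CLN2 were at -1.72 ± 0.25 and -1.79 ± 0.03, and CLB1 at -1.75 ± 0.18. HO was at -2.44 ± 0.31. The G1/S, G2/M and M/G1 lists had medians of -0.37, -0.32 and -0.28 (adjusted p = 0.0072, 0.0049 and 0.0049; with an estimated correlation adjusted p = 0.28, 0.13 and 0.1). The mitochondrially encoded transcripts had a median of -0.45 and were not called (adjusted p = 0.2).

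In limma, 2182 of 5301 genes passed after thermal neutrons, 1056 higher and 1126 lower, and 336 changed at least 2-fold. The majority turned here too with median centring, with 1125 higher and 998 lower. The count was 1445 without replicate 3. Of 38 lists, 8 shifted up and 7 down, and 6 of the 15 (ubiquitin and autophagy, proteasome, stress-induced, chaperones, phosphate and DNA damage inducible) were also called with an estimated correlation. Purine biosynthesis (median -0.33; adjusted p = 0.082 with an estimated correlation) was no longer called without replicate 3 (0.056).

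After fast neutrons HUG1 rose 7.25-fold (2.86 ± 0.49, adjusted p = 0.0014), RNR4 5.85-fold (2.55 ± 0.26) and RNR2 4.64-fold (2.22 ± 0.37). HSP12 rose 5.29-fold (2.40 ± 0.33) and AHP1 (YLR109W) 2.58-fold (1.37 ± 0.30). Of the DNA damage inducible genes 12 of 31 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.40 (adjusted p = 1.1e-04; 9.3e-06 with an estimated correlation). Stress-induced genes rose in 15 of 52 and fell in 1 (18 and 2 adjusted over the list alone), with CYC7 at 1.27 ± 0.15 and a median of 0.33 (adjusted p = 1.1e-04; adjusted p = 0.13 with an estimated correlation). Oxidative stress defence genes rose in 13 of 39 and fell in 2 (18 and 3 adjusted over the list alone), with a median of 0.38 (adjusted p = 3.0e-04; 0.011 with an estimated correlation). Proteasome genes rose in 6 of 37 and fell in 0 (10 and 1 adjusted over the list alone), with a median of 0.31 (adjusted p = 4.9e-04; 1.0e-04 with an estimated correlation).

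SCW11 was at -2.06 ± 0.46 after fast neutrons, DSE1 at -1.87 ± 0.18, EGT2 (YNL327W), a cell separation gene, at -1.77 ± 0.14 and DSE4 (YNR067C), a daughter cell glucanase, at -1.66 ± 0.08. In the M/G1 list 10 of 21 members fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.72 (adjusted p = 1.5e-07; 9.2e-04 with an estimated correlation). CHA1 (YCL064C), a serine and threonine deaminase, was at -1.94 ± 0.17, the amino acid permeases DIP5 (YPL265W) and AGP1 (YCL025C) at -1.63 ± 0.17 and -1.59 ± 0.20, and GLN1 (YPR035W), glutamine synthetase, at -1.47 ± 0.23. Amino acid biosynthesis genes fell in 22 of 60 and rose in 1 (26 and 2 adjusted over the list alone), with LYS9 at -1.33 ± 0.26, GDH1 at -1.16 ± 0.13 and a median of -0.38 (adjusted p = 1.5e-07; 5.8e-06 with an estimated correlation). The G1/S list had 6 of 35 members lower and 1 higher (12 and 2 adjusted over the list alone), with BUD9 at -1.40 ± 0.22, EXG1 at -1.33 ± 0.23 and a median of -0.31 (adjusted p = 8.4e-04; 2.1e-04 with an estimated correlation). Purine biosynthesis genes fell in 8 of 19 and rose in 0 (9 and 0 adjusted over the list alone), with a median of -0.43 (adjusted p = 1.5e-04; 0.0089 with an estimated correlation). Histone genes fell in 5 of 10 and rose in 0 (7 and 0 adjusted over the list alone), with a median of -0.66 (adjusted p = 2.9e-04; adjusted p = 0.14 with an estimated correlation). The mitochondrially encoded transcripts fell in 4 of 6 and rose in 0 (5 and 0 adjusted over the list alone), with ATP6 at -1.27 ± 0.14. Their median was -0.91 (adjusted p = 2.3e-04, and 9.2e-04 with an estimated correlation), with list medians of -1.29, -0.59 and -0.88 on the single arrays. Priming on a poly(A) tail should deplete these transcripts in both channels of an array. It bears on how well they were measured, and whether it affects the ratio was not tested.

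In limma, 630 of 4936 genes passed after fast neutrons, 304 higher and 326 lower, and 116 changed at least 2-fold. This count depended strongly on which arrays were used: it was 68 without replicate 1, 1652 without replicate 2 and 62 without replicate 3. It was 35 with the high-power scans alone, 1323 with the low-power scans alone, 988 with arrays scaled to the same spread and 1732 with array weights. The high-power scan of replicate 2 had a median of 0.134, and without that scan, an alternative chosen after seeing the data, the count was 1391. Of 37 lists, 7 shifted up and 7 down, and 8 of the 14 (amino acid, DNA damage inducible, M/G1, G1/S, mitochondrially encoded, proteasome, purine and oxidative stress) were also called with an estimated correlation. Without replicate 1 the calls ended for chaperones (median -0.23; adjusted p = 0.074), cytosolic ribosomal proteins (0.25; 0.074) and ubiquitin and autophagy (0.26; 0.061), and without replicate 2 for the last (0.16). The adjusted p with an estimated correlation was 0.34, 0.5 and 0.13.

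**Figure D1:**
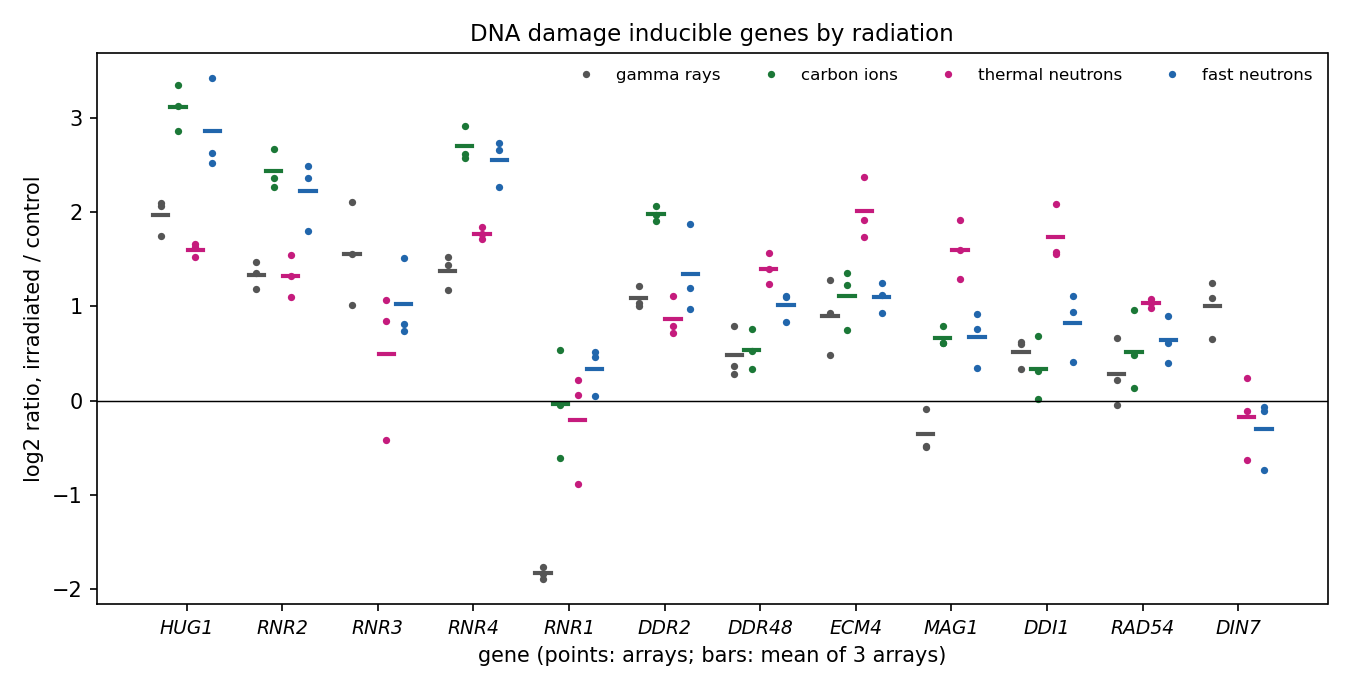
Log2 ratio of irradiated over control for 12 DNA damage inducible genes after each radiation, with points for single arrays and bars for the mean of 3 arrays. HUG1 averages 1.97 after gamma rays, 3.11 after carbon ions, 1.60 after thermal neutrons and 2.86 after fast neutrons, and RNR1 lies at -1.83 after gamma rays.

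**Figure D2:**
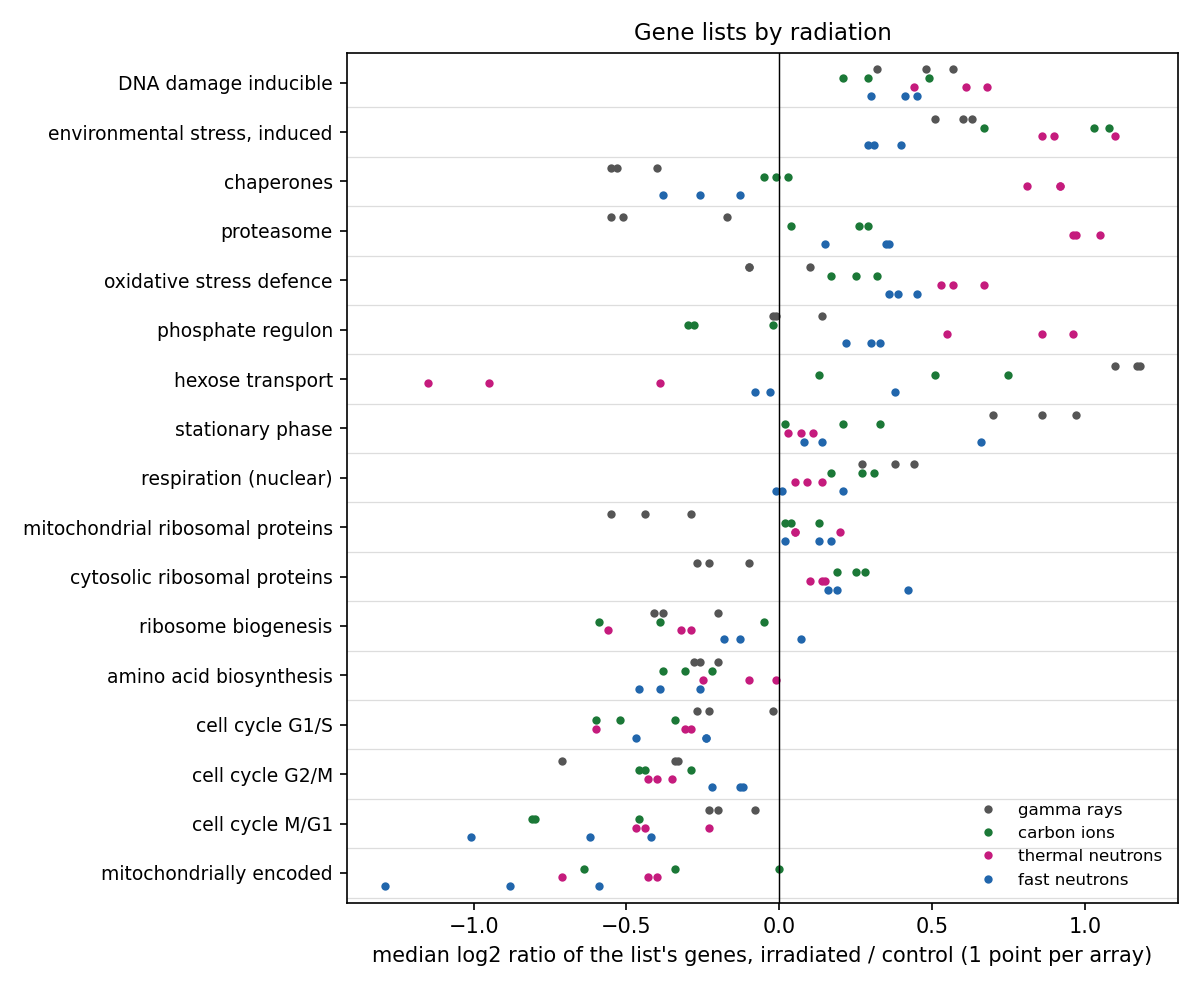
Median log2 ratio of 17 gene lists, with 1 point per array and radiation. The proteasome list has a median of 1.02 after thermal neutrons and -0.37 after gamma rays, and the hexose transport list one of -0.86 and 1.03.

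Most chaperone, proteasome and hexose transport genes differed between thermal neutrons and gamma rays. The labelled dose also differed (20.8 Gy and 17 Gy), as did the scans, since gamma ray arrays had a single scan. Neither can be told apart from the radiation. SSA4 was higher after thermal neutrons by log2 4.75 (95% confidence interval 4.40 to 5.10, adjusted p = 2.9e-09), HSP104 by 4.10 (3.51 to 4.70) and HSP42 by 4.00 (3.61 to 4.39). ARO9 was higher by 4.05 (3.58 to 4.52). HXT2 differed by -4.46 (-5.51 to -3.41), SUC2 by -4.15 (-4.67 to -3.62), JEN1 by -3.79 (-4.32 to -3.27) and MAL32, a maltase, by -3.73 (-4.51 to -2.94). Chaperone genes were higher after thermal neutrons in 32 of 39 and lower in 3 (33 and 3 adjusted over the list alone), with a median difference of 1.93 (adjusted p = 2.3e-15; 2.9e-04 with an estimated correlation). Proteasome genes were higher in 36 of 37 (36 adjusted over the list alone), with a median difference of 1.38 (adjusted p = 1.1e-16; 0.013 with an estimated correlation). Ubiquitin and autophagy genes were higher in 17 of 25 and lower in 1 (19 and 1 adjusted over the list alone), with a median difference of 0.94 (adjusted p = 2.4e-05; 6.4e-06 with an estimated correlation). Hexose transport genes were lower in 18 of 21 (19 adjusted over the list alone), with a median difference of -2.41 (adjusted p = 1.1e-11; adjusted p = 0.14 with an estimated correlation). Of the DNA damage inducible genes MAG1 was higher by 1.95 (1.53 to 2.38), DDI1 by 1.22 (0.76 to 1.68) and RNR1 by 1.63 (0.96 to 2.29). Of that list 10 of 33 members were higher and 6 lower (10 and 6 adjusted over the list alone), and camera did not call it against other genes (median difference 0.13, adjusted p = 0.36). DIN7, a nuclease, differed by -1.16 (-1.76 to -0.56), while the difference for HUG1 did not pass (-0.37, adjusted p = 0.12). In limma 1924 of 4843 genes differed, 1026 higher and 898 lower after thermal neutrons, 734 of them at least 2-fold. Of 36 lists 11 differed, and 3 (chaperones, proteasome, ubiquitin and autophagy) also did with an estimated correlation.

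**Figure D3:**
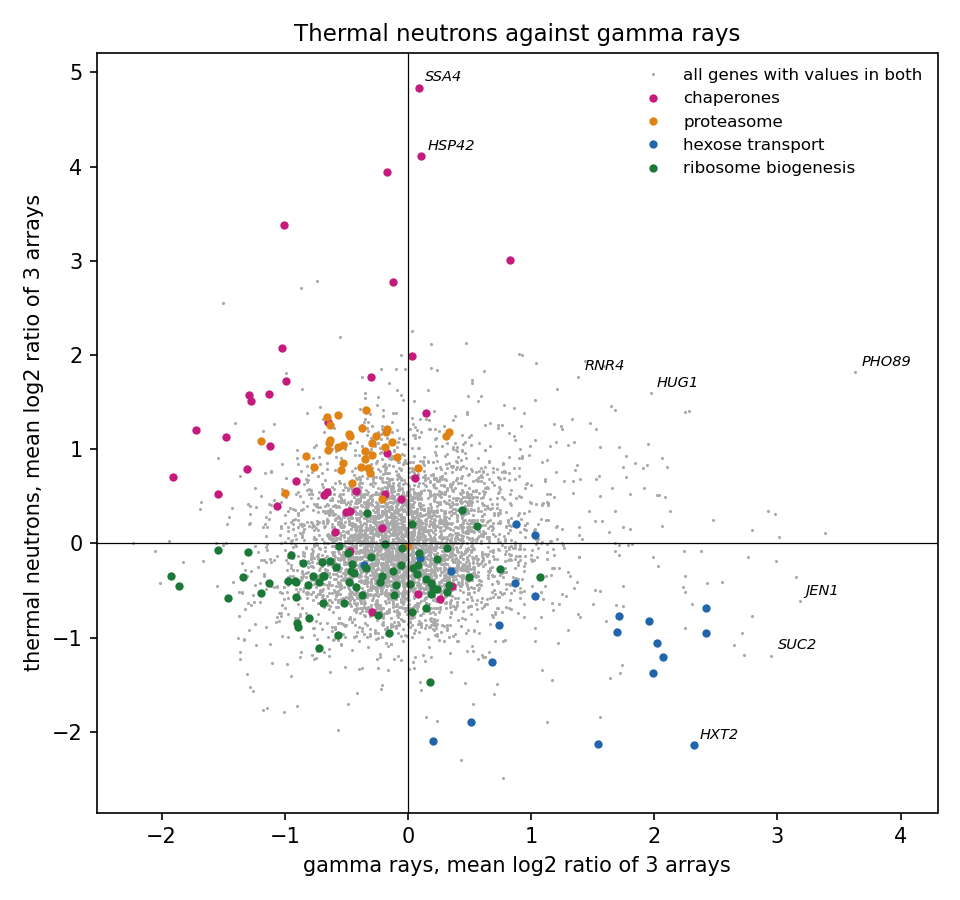
Mean log2 ratio after thermal neutrons against that after gamma rays for 4843 genes, with chaperone, proteasome, hexose transport and ribosome biogenesis genes in colour. Across genes r is 0.05, and SSA4 lies at 4.84 after thermal neutrons and 0.09 after gamma rays.

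By the labels carbon ions were given in 10 min in 5 ml of saline and gamma rays over 20.5 h in 2 ml. In the differences between them, exposure time and saline volume cannot be told apart from the radiation. TYE7 was higher after carbon ions than after gamma rays by log2 2.34 (1.83 to 2.85, adjusted p = 9.6e-05), HSP12 by 2.21 (1.74 to 2.68) and AHA1 by 1.93 (1.52 to 2.33). POT1 (YIL160C), the thiolase of fatty acid oxidation, differed by -3.00 (-3.51 to -2.50), PHO89 by -2.96 (-3.49 to -2.43), JEN1 by -2.91 (-3.44 to -2.39) and NCE103 by -2.81 (-3.43 to -2.18). HUG1, RNR4 and RNR2 were higher after carbon ions by 1.14, 1.32 and 1.10 (adjusted p = 0.0015, 4.6e-04 and 0.0018), and RNR1 by 1.79 (0.0021). CDC9 and PCL5 were lower (-0.82 and -0.80, adjusted p = 0.01 and 0.047). Of the DNA damage inducible list 8 of 30 members were higher and 2 lower (9 and 5 adjusted over the list alone). Camera did not call it against other genes (median difference 0.20, adjusted p = 0.22). Cytosolic ribosomal protein genes were higher in 58 of 124 and lower in 0 (63 and 1 adjusted over the list alone), with a median difference of 0.48 (adjusted p = 3.0e-12; 0.015 with an estimated correlation). Chaperone genes were higher in 20 of 36 and lower in 1 (20 and 1 adjusted over the list alone), with a median difference of 0.60 (adjusted p = 1.1e-07; 0.027 with an estimated correlation). M/G1 genes were lower in 9 of 20 and higher in 0 (9 and 0 adjusted over the list alone), with a median difference of -0.47 (adjusted p = 4.6e-06; 0.013 with an estimated correlation). Hexose transport genes were lower in 14 of 22 and higher in 1 (14 and 1 adjusted over the list alone), with a median difference of -0.90 (adjusted p = 3.3e-05; adjusted p = 0.39 with an estimated correlation). In limma 1093 of 4750 genes differed, 596 higher and 497 lower after carbon ions, 295 of them at least 2-fold, and the count was 606 without carbon ions replicate 1 and 657 without gamma rays replicate 3. Of 36 lists 13 differed and 4 also did with an estimated correlation: those for M/G1, chaperones and cytosolic ribosomal proteins, and ubiquitin and autophagy, whose call ended without carbon ions replicate 2 (adjusted p = 0.12) and without gamma rays replicate 2 (0.06) or 3 (0.079).

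Most chaperone, proteasome, phosphate regulon and hexose transport genes differed between thermal neutrons and carbon ions. Here too the labelled exposure differed, with 20 h in 2 ml of saline for thermal neutrons and 10 min in 5 ml for carbon ions. It cannot be told apart from the radiation. SSA4 was higher after thermal neutrons by log2 4.15 (3.80 to 4.50, adjusted p = 3.8e-08), HSP42 by 3.06 (2.67 to 3.45) and HSP104 by 3.03 (2.43 to 3.64). RCK1 (YGL158W), a protein kinase of the oxidative stress response, differed by -3.25 (-4.00 to -2.50), HXT2 by -3.03 (-4.11 to -1.95) and HXT4 by -2.91 (-3.69 to -2.14). HUG1, RNR2, DDR2 and RNR4 were lower after thermal neutrons (-1.51, -1.11, -1.11 and -0.92, adjusted p = 5.6e-04, 0.0033, 0.0021 and 0.0064). DDI1, MAG1, ECM4, DDR48 and RFA2 were higher by 1.40, 0.93, 0.90, 0.86 and 0.79 (adjusted p = 0.0023, 0.013, 0.039, 0.016 and 0.027). Of the DNA damage inducible list 5 of 32 members were higher and 4 lower (6 and 4 adjusted over the list alone). Camera did not call that list against other genes (median difference 0.05, adjusted p = 0.75). Chaperone genes were higher in 20 of 36 and lower in 0 (27 and 1 adjusted over the list alone), with a median difference of 0.67 (adjusted p = 6.6e-17; 6.9e-05 with an estimated correlation). Proteasome genes were higher in 23 of 37 and lower in 0 (34 and 0 adjusted over the list alone), with a median difference of 0.81 (adjusted p = 2.9e-17; 0.0079 with an estimated correlation). Phosphate regulon genes were higher in 14 of 17 and lower in 0 (14 and 0 adjusted over the list alone), with a median difference of 0.94 (adjusted p = 7.1e-11; 6.8e-04 with an estimated correlation). Hexose transport genes were lower in 13 of 21 and higher in 0 (14 and 0 adjusted over the list alone), with a median difference of -1.21 (adjusted p = 7.1e-11; adjusted p = 0.1 with an estimated correlation). In limma 542 of 5033 genes differed, 306 higher and 236 lower after thermal neutrons, 191 of them at least 2-fold. The count was 226 and 219 without thermal neutrons replicate 1 and 2, and 224 and 267 without carbon ions replicate 1 and 2. Of 37 lists 14 differed and 5 also did with an estimated correlation, namely chaperones, phosphate, proteasome, ubiquitin and autophagy, and sulfur assimilation (median difference 0.22, no longer called without carbon ions replicate 3, adjusted p = 0.052).

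Genes that passed in the same direction after all 4 radiations included HUG1, RNR2, RNR4 and CYC7 among those that rose. Among those that fell were SCW11 (-0.64 ± 0.06 after gamma rays, -1.98 ± 0.29 after carbon ions, -1.19 ± 0.15 after thermal neutrons and -2.06 ± 0.46 after fast neutrons), EGT2 and CLN2. Of 4420 genes tested in all, 40 were higher in all 4, where independent sets would give 0.972, and 53 were lower, where they would give 2. The count of 93 was 22 without fast neutrons replicate 1, 144 without replicate 2 and 14 without replicate 3, and 55 with a 1.5-fold limit and the same sign on all arrays in place of the test. Mean log2 ratios correlated across genes with r = 0.60 between carbon ions and fast neutrons, 0.51 between carbon ions and thermal neutrons, 0.51 between thermal and fast neutrons, 0.42 between gamma rays and carbon ions, 0.18 between gamma rays and fast neutrons and 0.05 between gamma rays and thermal neutrons (Spearman rho 0.58, 0.54, 0.53, 0.35, 0.14 and 0.06). The dye orientation was the same on all arrays, so a dye effect adds to these counts and correlations.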

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

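The set tests of differences between radiations and the tests of explanations, apart from that of saturated spots, were chosen after the results had been seen.

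Lists called up after 1 radiation and down after another, and differing between them, were looked at more closely. A dye effect common to all arrays cancels in these differences by design, and no test of it was made. Hexose transport genes had a median of 1.03 after gamma rays and -0.86 after thermal neutrons, with a median difference of -2.41 (camera adjusted p = 1.1e-11; adjusted p = 0.14 with an estimated correlation). A long stay in cold saline was labelled for both radiations, with about the same exposure time. Taken as labelled, its length alone does not part them. The labelled 20.5 h for gamma rays, however, does not match their labelled dose and dose rate. The list median of -0.86 after thermal neutrons (-1.15, -0.95 and -0.39 on the 3 arrays) belongs to the pattern as it was chosen. It is therefore no separate test of the stay in saline. A different glucose supply or growth state of irradiated and control cultures stays open, as may the radiation itself: the lowest list median on 1 array of gamma rays was 1.10 and the others were 1.17 and 1.18, which either would give.

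Chaperone genes had a median of 0.79 after thermal neutrons and -0.47 after gamma rays, with a median difference of 1.93 (adjusted p = 2.3e-15; 2.9e-04 with an estimated correlation). Proteasome genes had medians of 1.02 and -0.37 and a median difference of 1.38 (adjusted p = 1.1e-16; 0.013 with an estimated correlation). For saturated spots in the high-power scan, the low-power scan alone gave a proteasome median of 1.01 beside 1.02 in both scans. The chaperone median was 0.67 in each, over the 36 proteasome and 34 chaperone members measured in the low-power scan. The rise after thermal neutrons thus did not rest on the high-power scan. The value for both scans includes the low-power scan. Gamma ray arrays had a single scan, so the fall after gamma rays could not be checked in this way. A temperature that differed between irradiated and control cells during exposure stays open. The lowest median of either list on 1 array of thermal neutrons was 0.81, which a warmer sample or the radiation could give, and the labels do not part them.

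M/G1 genes were lower after carbon ions than after gamma rays (median difference -0.47, adjusted p = 4.6e-06; 0.013 with an estimated correlation). Slower growth as a whole is argued against by the cytosolic ribosomal protein genes only, which were higher after carbon ions by a median of 0.48 (0.015 with an estimated correlation). Camera did not call ribosome biogenesis (median difference -0.00, adjusted p = 0.95) or RNA polymerase I and III (0.20, adjusted p = 0.24), so these lists do not decide it. The labelled exposure time and saline volume also differed between carbon ions and gamma rays and cannot be told apart from the radiation. Cells held at another stage of the cell cycle may still account for it, but the G2/M genes do not decide this: 10 of 18 members were lower after carbon ions than in the controls and 8 of 16 after gamma rays, with 0 higher in either, and the list was not called between the 2 radiations (median difference -0.08, adjusted p = 0.37). Of the G1/S genes 8 of 28 were lower and 1 higher after carbon ions than after gamma rays (8 and 1 adjusted over the list alone; median difference -0.42, adjusted p = 0.048; adjusted p = 0.53 with an estimated correlation), a call that ended without carbon ions replicate 1 (adjusted p = 0.11) or 2 (0.14) or gamma rays replicate 2 (0.2) and under 6 other alternatives (0.051 to 0.088).

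The other lists called in opposite directions after 2 radiations were cytosolic ribosomal proteins (0.28 after carbon ions and -0.18 after gamma rays, median difference 0.48, adjusted p = 3.0e-12; 0.15 after thermal neutrons, median difference 0.35 from gamma rays, adjusted p = 1.9e-04 and adjusted p = 0.24 with an estimated correlation). After thermal neutrons that list had 25 of 124 members higher and 8 lower (17 and 6 adjusted over the list alone), and its own call (adjusted p = 0.013) was lost with an estimated correlation (adjusted p = 0.33). After gamma rays its call was lost in the same way (adjusted p = 0.34). Proteasome genes differed between carbon ions and gamma rays by a median of 0.53 (0.24 and -0.37, adjusted p = 5.9e-08; adjusted p = 0.14 with an estimated correlation). Hexose transport genes differed between thermal neutrons and carbon ions by a median of -1.21 (-0.86 and 0.41, adjusted p = 7.1e-11; adjusted p = 0.1 with an estimated correlation). Among probes with no gene symbol, which enter no comparison of the report, 116 of 272 passed after gamma rays, 63 of 427 after carbon ions, 95 of 497 after thermal neutrons and 16 of 417 after fast neutrons.

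With 3 arrays there are 4 sign patterns, and with 3 against 3 there are 10 splits, too few for a share under 0.05. The real sign pattern, 1 of the 4 with as many genes, gave 1958 genes for gamma rays, 1105 for carbon ions, 2182 for thermal neutrons and 630 for fast neutrons, and the highest of the others gave 0 in each. The real split, 1 of the 10 with as many genes, gave 1093 between carbon ions and gamma rays, 1924 between thermal neutrons and gamma rays and 542 between thermal neutrons and carbon ions, and the highest of the others gave 0, 0 and 25.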

How the results depend on the processing

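Leaving out the least correlated high-power scan and the set tests of differences between radiations were chosen after the results had been seen. No named gene or list that had been called changed direction, while median centring turned the majority of called genes for 3 radiations. Of 573 named genes by radiation 373 passed under all alternatives, of 65 named genes in a difference 53, of 62 shifted lists 22 and of 38 lists in a difference 10. Of the 62 calls lost by shifted lists 40 were lost with an estimated correlation and 17 by leaving out a replicate. Stricter thresholds lower a count by construction: adjusted p under 0.01 gave 1181 genes for gamma rays, 382 for carbon ions, 1252 for thermal neutrons and 40 for fast neutrons, and a 2-fold limit gave 343, 124, 336 and 116, and 295, 734 and 191 for carbon ions against gamma rays, thermal neutrons against gamma rays and thermal neutrons against carbon ions. Carbon ions gave 1675 genes with scaled arrays, 2165 with array weights and 532 fitted alone (the cause was not tested), while gamma rays and thermal neutrons fitted alone gave 1891 and 2337. Fast neutrons gave 35 with high-power scans, 1323 with low-power scans, 988 with scaled arrays and 1732 with array weights (the cause was not tested). They gave 1391 without the high-power scan of replicate 2, beside 630 in the reported fit, so including that scan lowered the count. With an estimated correlation 3, 5, 6 and 8 lists shifted after gamma rays, carbon ions, thermal neutrons and fast neutrons (the cause was not tested). For lists with an estimate of 0, such as DNA damage inducible, that run was less strict than the main test. Leaving out a replicate gave 1307 to 1655 genes for gamma rays, 371 to 1053 for carbon ions, 1445 to 1492 for thermal neutrons and 62 to 1652 for fast neutrons. It gave 606 to 951 for carbon ions against gamma rays, 219 to 635 for thermal neutrons against carbon ions, and for genes shared by all 4 radiations 14 to 144. A 1.5-fold limit in place of the test gave 55 shared genes (the cause was not tested). Median centring moved the share of higher genes from 44% to 51.1% for gamma rays, from 44.8% to 54.7% for carbon ions, from 48.4% to 53% for thermal neutrons and from 48.3% to 44.6% for fast neutrons. Differences from fast neutrons were not run, since the array types differ, and fitting fast neutrons alone is the reported fit. Spots without a value, 4496 to 6133 values of 6912 probes per column, limit which genes were tested.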

Other observations

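The test of dose and the adjustment of the fry tests were chosen after the results had been seen, and so were the genes named here outside the lists.

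Camera, which compares a list with other genes, called none of the 5 lists of DNA repair genes nor the checkpoint list after any of the 4 radiations (24 tests, adjusted p from 0.097 to 0.94; 1 had an unadjusted p under 0.05). Fry in limma, which asks whether a list moves on balance without comparing it with other genes, gave p adjusted over the lists of a radiation under 0.05 for 6 of these tests. After thermal neutrons homologous recombination (median 0.27, adjusted p = 0.023), nucleotide excision repair (0.24, adjusted p = 0.021) and translesion and postreplication repair (0.08, adjusted p = 0.038) were up, with the median above 0 on all 3 arrays. After gamma rays homologous recombination was up (0.08 and above 0 on all 3 arrays, adjusted p = 0.031), translesion and postreplication repair down (-0.29 and below 0 on all 3 arrays, adjusted p = 0.049) and nucleotide excision repair down with a mean of -0.08 and a median of 0.03, below 0 on 2 arrays (adjusted p = 0.049). After gamma rays LIF1, which works with DNA ligase IV, was at 1.28 ± 0.33 and RAD55, a recombination mediator, at 0.94 ± 0.12, while RAD3, a repair helicase, was at -1.02 ± 0.02 and RAD6, a ubiquitin conjugase, at -1.19 ± 0.20. After thermal neutrons UBC13 and MMS2, which together build ubiquitin chains in tolerance of damage, were at 1.23 ± 0.23 and 1.07 ± 0.14. Of the checkpoint list 6 of 19 members were lower after thermal neutrons and 1 was higher (8 and 1 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.3): CHK1, a checkpoint kinase, and PDS1, securin, were at -0.68 ± 0.02 and -0.89 ± 0.31, and RAD53, another checkpoint kinase, at 0.94 ± 0.17. After carbon ions the checkpoint genes CHK1 and TOF1 were at -0.67 ± 0.10 and -0.94 ± 0.29.

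The iron regulon had 10 of 30 members higher and 7 lower after thermal neutrons (10 and 7 adjusted over the list alone), with FIT2, a cell wall mannoprotein, at 2.79 ± 0.47 and FET4, an iron transporter, at -1.04 ± 0.21 (adjusted p = 0.64). Sulfur assimilation had 10 of 29 higher and 6 lower (11 and 7 adjusted over the list alone), with MET6, methionine synthase, at 1.27 ± 0.34 (adjusted p = 0.2). After gamma rays the phosphate regulon had 7 of 18 higher and 4 lower (7 and 5 adjusted over the list alone), with the acid phosphatases PHO5 and PHO11 at 1.30 ± 0.24 and 1.48 ± 0.22 and PHM8, a nucleotidase, at -0.86 ± 0.21 (adjusted p = 0.24). Of the alpha mating genes SAG1, the agglutinin, and STE3, the a-factor receptor, were at -1.04 ± 0.05 and -0.82 ± 0.14 after thermal neutrons (list median -0.41, adjusted p = 0.17). The sign of the list median, the mean or the test differed in 12 tests of a list after a radiation and in 6 of a difference, none of which camera called (lowest adjusted p = 0.48 and 0.37). Among them were the iron regulon after thermal neutrons (median -0.14, mean 0.13) and oxidative stress after gamma rays (median -0.12, mean 0.04).

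Whether dose alone accounts for the different sizes of the HUG1, RNR2 and RNR4 rise cannot be decided from these values. Each labelled dose goes with 1 kind of radiation, and for carbon ions exposure time and saline volume differed too. Dose cannot be told apart from these. After carbon ions, with the highest labelled dose (25 Gy), HUG1, RNR2 and RNR4 were higher than after gamma rays by 1.14, 1.10 and 1.32, and they were lower after thermal neutrons than after carbon ions (-1.51, -1.11 and -0.92), all on the side of the higher dose and all passing. HUG1 differed between thermal neutrons (20.8 Gy) and gamma rays (17 Gy) by -0.37 (-0.76 to 0.02), RNR2 by -0.01 (-0.41 to 0.38) and RNR4 by 0.40 (0.03 to 0.76, adjusted p = 0.079), of which only the last lies on the side of the higher dose. The labelled 20.8 Gy goes with a global rate of 17 mGy/min, of which thermal neutrons gave 1.0 to 2.0 mGy/min. After fast neutrons (20.3 Gy) HUG1, RNR2 and RNR4 were at 2.86, 2.22 and 2.55 beside 1.60, 1.32 and 1.77 after thermal neutrons, larger at the slightly lower labelled dose, in separate tables and not tested.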
